A study of Drosophila melanogaster with 2 samples.

How the data were processed

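Whole embryos of a transgenic Drosophila line expressing an Eip74EF fusion to enhanced green fluorescent protein were profiled by ChIP-seq with an antibody against the tag. Per the labels, embryos were of mixed sex and aged 8 to 16 h, chromatin was sheared by sonication to a size range of 200 to 800 bp, and the 2 samples are biological replicates 3 and 1 of the same line. A separate age field of the labels holds a number that cannot be an embryo's age in hours and was not used. Both samples formed 1 group. The IDR, pooled and replicate peak lists were analysed; signal tracks and alignments were not analysed here.

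Per the deposited file descriptions, the authors called peaks on the alignments of each replicate with a control library and on the alignments of both replicates pooled with the same kind of control, and derived the IDR list from these 3 lists, all on assembly dm6. The aligner, the peak caller, the IDR threshold and their versions are not given in the sources used here. Each deposited list gives a peak's interval, a signal value, a −log10 of a q-value and the offset of the summit. The signal is the authors' value relative to the control, on a scale that the depth of each list can set, so it was used only to rank or describe peaks within a list, except for the replicate comparison, where it was set side by side as a rank and a ratio. The deposited −log10 q-values were not used to rank peaks, because all 5004 IDR peaks share the highest value, 4.18. The replicate and pooled lists hold exactly 30000 peaks each, which looks like a fixed limit, so their lengths carry no information on how much was bound. The IDR list was found to be exactly the 5004 peaks of highest signal in the pooled list. Of these, 93 shared an interval with another peak and 3 had a summit at or past the end of the interval, so summits and not intervals were counted. No read counts were used, so the depth per sample is unknown. The number of samples limits what can be said of variation between embryos, and binomial intervals (exact Clopper-Pearson, 95%) cover counting error over peaks or genes only.

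Summits were placed on the Ensembl release 115 annotation (BDGP6.54), which describes the same assembly as dm6, and on the matching reference sequence. Arms 2L, 2R, 3L, 3R, 4 and X were used, and no listed peak lay elsewhere. Each summit was put into the first matching class of promoter (within 500 bp of a protein-coding TSS), 5′ UTR, 3′ UTR, coding exon, intron, other exon and intergenic. Random positions were drawn 1000 times on the same arms among called bases, and two-sided permutation p-values were adjusted over the 7 classes by Benjamini-Hochberg. Regions where peaks cannot be called, such as repeats, were not left out of any random placement. Replicate lists were compared by the share of top peaks with a summit within 100 bp, against random placement. Motif strings were sought on both strands within 50 bp of summits and in windows of the same width centred 400 bp to either side, with an exact McNemar test against each flank, the larger p being reported, and adjustment over the 11 strings of the panel or over all hexamers. The ETS consensus was a test of its own.

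Gene lists were fixed before the data were examined, from textbook knowledge of ecdysone biology, of embryonic tissues and cell types and of housekeeping complexes, with symbols updated to the annotation where they had changed. A gene counted as bound at its promoter when a summit lay within 500 bp of any of its TSSs. In all, 2175 of 13945 protein-coding genes (15.6%) were bound in this way, and 3446 (24.7%) had a summit from 2 kb upstream to the gene's end. Promoter counts were tested by Fisher's exact test, two-sided, over 24 lists (tRNA genes against all other genes), and gene body counts against 10000 random lists matched on gene length decile, over 23 lists. Peaks near a TSS shared by several genes count for each of them. Signal at promoters and elsewhere was compared by permuting peaks 100000 times, and the X to autosome ratio was bootstrapped over 100 kb blocks 1000 times. The genes named were set by rule: Eip74EF, each ecdysone response gene with a summit, up to 3 members of every other list with the strongest promoter peak, the 10 strongest peaks, the 5 strongest over 2 kb from a TSS and the 3 densest 20 kb windows. Outside this rule, aop is named as an ETS factor, as are the window over shot and the genes ranked by number of summits in the other observations. All of these were named after their values were seen.

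The steps named here were tested on simulated data. For the promoter share, 1 of 20 random peak sets of 5004 peaks was called and 20 of 20 sets with planted promoter peaks were. For the ETS motif test, 0 of 20 random sets and 20 of 20 sets with planted strings were called. For promoter lists over 13945 genes, 200 of 200 planted lists and 4 of 280 random lists were called, and for gene bodies 0 of 480 random lists of long genes were. For replicate overlap, 1 of 20 independent random sets and 20 of 20 with planted shared summits were called. For windows of dense peaks, 0 of 20 random and 20 of 20 planted sets were called, and for promoter signal, 1 of 20 shuffled and 20 of 20 raised sets. In the hexamer scan, 0 of 10400 hexamers were called at random positions, and a planted CGGAAG came first in 5 of 5 sets. Random positions lack the drop in GC content that IDR summits had against their flanks. The motif and hexamer simulations therefore do not cover calls made by base composition. The random promoter lists were drawn without regard to TSS number, so calls made by that number were not covered either. The X to autosome ratio and the density over Eip74EF were not simulated, and no bound gene bodies were planted. Alternatives covered a stricter peak threshold, each replicate's list alone, TSS windows of 250 and 1000 bp, other overlap distances, other motif strings and windows, other backgrounds and the exclusion of shared promoters. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.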

Results

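Binding of the ecdysone-induced protein Eip74EF was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole Drosophila melanogaster embryos of mixed sex aged 8 to 16 h. Eip74EF is an ETS-domain transcription factor of the response to the steroid hormone ecdysone. The embryos came from a transgenic line that stably expressed Eip74EF fused at its C terminus to enhanced green fluorescent protein, and the fusion protein was precipitated with an antibody against the fluorescent tag. The samples formed 1 group of 2 biological replicates, numbered 1 and 3 by their labels. No untreated, untagged or control samples were among them, so no comparison between groups was made, and the comparisons below set peak positions against random positions, flanking sequence or other genes. The measured values were deposited peak lists, 1 for each replicate, 1 for the pooled replicates and 1 that had passed the irreproducible discovery rate (IDR) step of the authors. Read counts were not among the values analysed here, so the depth of each sample is unknown. Peaks are regions of the genome and not replicates, and binomial intervals over peaks or genes cover counting error only. All coordinates are on assembly dm6.

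The IDR list held 5004 peaks with a median width of 427 bp. Peak signal, the authors' own value for each peak, ran from 184.6 to 3792 with a median of 282.5. The strongest peak had a summit at 3L 4824648, in an intron of Dhc64C, a dynein heavy chain gene, at 13.4 times the median signal. The second had its summit at X 2703883, 31 bp from a transcription start site (TSS) of the UDP-galactose transporter gene Ugalt, with a signal of 3224, and the third at X 15867979, 166 bp from the TSS of the glycolytic gene Gapdh2, with a signal of 3191. Of the remaining members of the strongest 10, the peaks nearest CG11050 (3027) and cbt (2783) lay in introns, the latter inside the neighbouring gene ush. Those nearest CG18549 (2614), px (2613), Pdrg1 (2500), PNPase (2463) and CG14100 (2458) lay within 500 bp of a TSS. The strongest peaks over 2 kb from any protein-coding TSS were in the 3′ UTR of stas (X 17625226, signal 2283), between genes, 11936 bp from the TSS of CG13323 (2R 13035320, 2092), and in introns of pxb (3R 15677915, 1855), CG12769 (2R 8061017, 1795) and Gug (3L 8458331, 1793).

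Both replicates gave largely shared peaks among the strongest, and less shared peaks at lower rank. Of the 5004 strongest peaks of replicate 1, 3397 (67.9%) had a summit within 100 bp of one of the 5004 strongest of replicate 3, against a mean of 0.754% and a maximum of 1.16% when the peaks of replicate 3 were placed at random within chromosome arms (permutation test, one-sided, p = 0.000999, the smallest that 1000 placements can give). The shared part was 87.6% among the top 250 peaks of each list and 49.8% among all 30000. The IDR list was derived from both replicate lists and the pooled list, so part of its overlap with them is built in. Of the IDR peaks, 4630 (92.5%) had a summit within 100 bp in both full replicate lists and 7 had one in neither. Across those 4630 regions, which are not independent replicates, the signals of both replicates had a Spearman correlation of 0.736 and a Pearson correlation of 0.812 on the log2 scale. The median distance between the paired summits was 24 bp, and the signal in replicate 3 was a median of 1.78 times that in replicate 1, on a scale that the depth of each library can set.

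**Figure D1:**
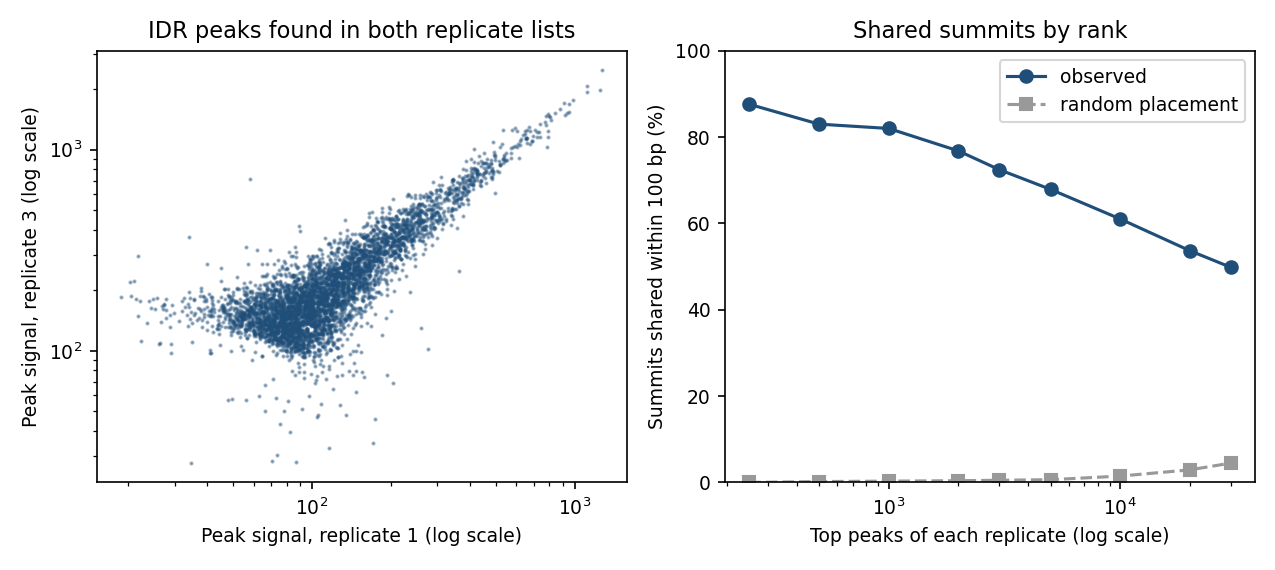
Left, peak signal in replicate 1 (x axis, log scale) against replicate 3 (y axis, log scale) for the 4630 IDR peaks found in both replicate lists, 1 point per peak. Right, share of replicate 1 summits within 100 bp of a replicate 3 summit (y axis, percent) for growing numbers of top peaks (x axis, log scale), observed (circles) and after random placement (squares); the observed share fell from 87.6% to 49.8%.

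Eip74EF-GFP peaks lay at promoters and in introns, and coding sequence was nearly free of them. Within 500 bp of a protein-coding TSS lay 2063 of the 5004 summits (41.2%, 95% exact binomial interval 39.9 to 42.6%), against 11.5% of random positions on the same arms, a ratio of 3.58 (permutation test, two-sided, p = 0.002, the smallest that 1000 sets can give). Only 14 summits (0.280%) lay in coding exons outside these promoter windows, against 13.3% of random positions, and 49 (0.979%) in 3′ UTRs, against 5.11% (permutation test, both adjusted p = 0.0035). Intergenic summits made up 14.01%, against 28.9% of random positions (permutation test, adjusted p = 0.0035). Introns held 2062 summits (41.2%), against 39.2% (permutation test, adjusted p = 0.014), but among the 5004 strongest peaks of replicate 1 alone the intron share was 37.4% and lay below that of random positions. Other exons, defined as those outside protein-coding genes, held 1.62% against 1.18% (permutation test, adjusted p = 0.021). Neither the intron call (40.5%) nor that of other exons (1.56%) was made among the 2502 strongest IDR peaks. The share in 5′ UTRs outside promoter windows, 0.679%, did not differ detectably from 0.781% (permutation test, adjusted p = 0.47). The median distance to the nearest protein-coding TSS was 938 bp, against 4158 bp for random positions. Random positions came from all called bases, also repeats where reads may not be placed uniquely. How far this adds to the lower intergenic share and the shorter distance was not tested.

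**Figure D2:**
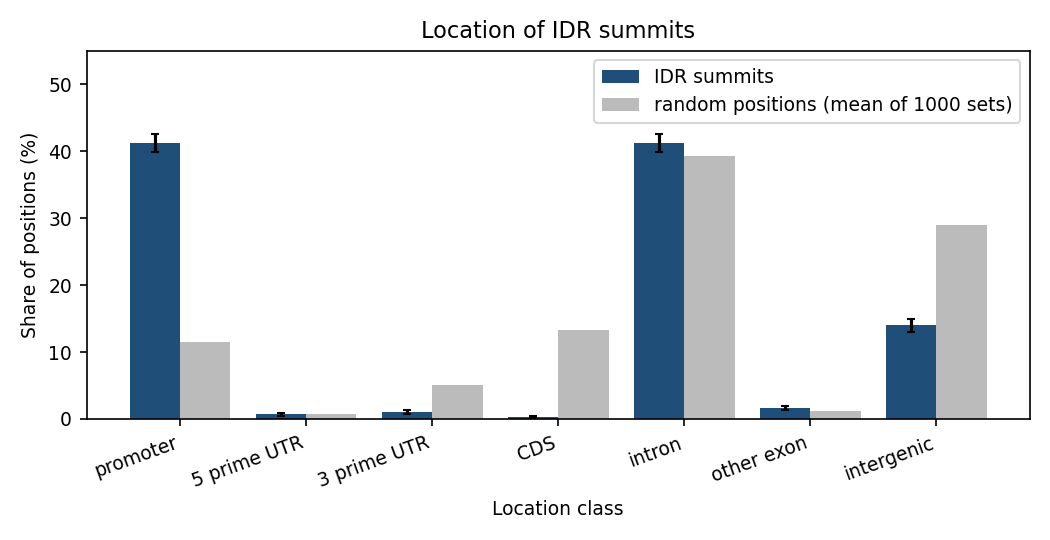
Share of IDR summits (dark bars, with 95% exact binomial intervals) and of random positions on the same arms (light bars, mean of 1000 sets) in each location class (x axis), in percent (y axis). Promoter windows held 41.2% of summits and 11.5% of random positions, and coding exons 0.280% and 13.3%.

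Peaks at promoters had slightly higher signal than peaks elsewhere, with medians of 290.3 and 277.4 (difference 12.9, permutation test over 100000 resamples, two-sided, p = 0.0051). The difference was 2.86 (permutation p = 0.081) among the strongest peaks of replicate 1 alone, on that list's own scale. By chromosome arm, peak density was 39.8 per Mb on 2L, 38.1 on 2R, 39.6 on 3L, 36.3 on 3R and 34.5 on X. The fourth chromosome, which is largely heterochromatic, held 16 peaks, or 11.9 per Mb. The X had 0.900 times the density of the large autosome arms, with a 95% bootstrap interval over 100 kb blocks of 0.772 to 1.02, so a difference was not detectable.

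Sequences of the ETS type stood at the summits. The consensus CCGGAAGT occurred within 50 bp of 38 summits (0.759%, 95% interval 0.538 to 1.04%) and in 0.130% of windows 400 bp to either side, a ratio of 5.85 (exact McNemar test, two-sided, larger p of both flanks = 9.25e-06). At promoter peaks alone the shares were 0.485% and 0.0969% on 10 peaks, and the exact test did not pass (p = 0.092), while outside promoters they were 0.952% and 0.153% (p = 0.00051); the difference between both classes was not tested. A shorter core was far more frequent. In the scan of all 2080 hexamers, CGGAAG was present at 7.31% of summits and 2.31% of flanks, a ratio of 3.17 (exact McNemar test, adjusted p = 9.37e-29), and it had the highest ratio among the 60 hexamers of its base composition. A scan of octamers was added after the data had been examined. There, 234 were more and 17 less frequent at summits, a balance opposite to that of hexamers. Octamers are rarer, with those named below in 0.0999% to 0.190% of flanks, which leaves little room for calls of lower frequency. Both balances are therefore not comparable. Of the 234, 17 contained at least 4 G or C bases, and 15 of those 17 held the ETS core GGAA. The foremost were ACTTCCGC (reverse complement GCGGAAGT, 1.60% of summits against 0.190% of flanks), CTTCCGCA (1.28% against 0.0999%) and ACCGGAAA (1.16% against 0.150%).

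Most of the sequences enriched at summits were AT-rich. Of 2080 hexamers, 289 were more and 573 less frequent at summits than at flanks at an adjusted p under 0.05, and the mean GC content within 50 bp of summits was 35.9%, against 42.5% and 42.0% at the left and right flanks. Among the strings fixed before the data were examined, the homeodomain-type string TAATTA was at 9.69% of summits and 6.46% of flanks (ratio 1.499, exact McNemar test, adjusted p = 1.98e-06). TAATTA holds only A and T and was not set against strings of its own base composition. Its higher share therefore cannot be told apart from the AT-richness of summits. The CA repeat CACACACA (2.70% against 3.93%, exact McNemar test, adjusted p = 0.0048) and the E-box CAGCTG (3.30% against 4.73%, adjusted p = 0.017) were less frequent at summits. The ratio for CAGCTG was 0.698, while the 59 other hexamers of the base composition of CGGAAG, equally rich in G and C, had a median of 0.647. Neither lower share can be told apart from the AT-richness of summits. The DREF-type string TATCGATA (0.719% against 0.330%) and the GATA-type string AGATAAGA (0.659% against 0.320%) did not pass the adjusted threshold, and neither did the GAGA repeat bound by Trl (2.50% against 3.25%; exact McNemar test, adjusted p = 0.11 for all 3). The strings of Zelda (0.480% against 0.649%), M1BP (0.380% against 0.210%) and nuclear receptors (AGGTCA, 1.86% against 2.23%, and CAAGGTCA, 0.180% against 0.200%) and the E-box CACGTG (1.02% against 1.30%) also did not pass. Among the strongest peaks of replicate 1 alone, 3 strings were higher at summits, the DREF and M1BP strings besides TAATTA, and CACACACA and CAGCTG were no longer past the threshold.

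**Figure D3:**
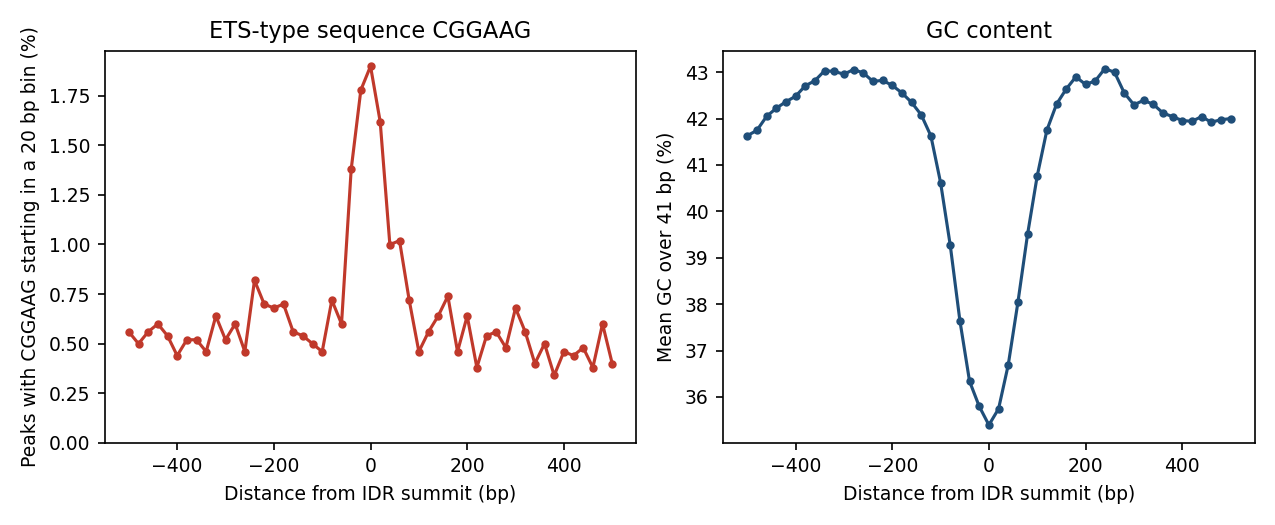
Left, share of the 5004 IDR peaks with CGGAAG on either strand starting in a bin of 20 bp (y axis, percent) by distance from the summit (x axis, bp). Right, mean GC content over 41 bp (y axis, percent) by the same distance; CGGAAG rose to 1.90% and GC fell to 35.4% at the summit.

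The Eip74EF gene itself had the highest density of IDR peaks among long genes. Over the gene (FBgn0000567, minus strand, 3L 17558672 to 17619325) and 20 kb to either side lay 33 IDR peaks, or 3.28 per 10 kb, against a median of 0.211 over the 224 other protein-coding genes of at least its length, all of which had a lower density. Of these peaks 27 lay within the gene and 6 in the flanks, and by location class 27 were intronic and 6 at promoters. The strongest, with its summit at 3L 17606815 and a signal of 1318, and the next, at 3L 17567007 with 1163, were both intronic. The unthresholded lists held 64 peaks in replicate 1 and 62 in replicate 3 over the same interval, above 97.3% and 95.5% of the other genes in density. The unthresholded pooled list held 59, above 93.75% of them in density and 85.3% in count. The labels do not say whether the tagged line carries a further copy of Eip74EF sequence, reads from which would map to this locus.

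**Figure D4:**
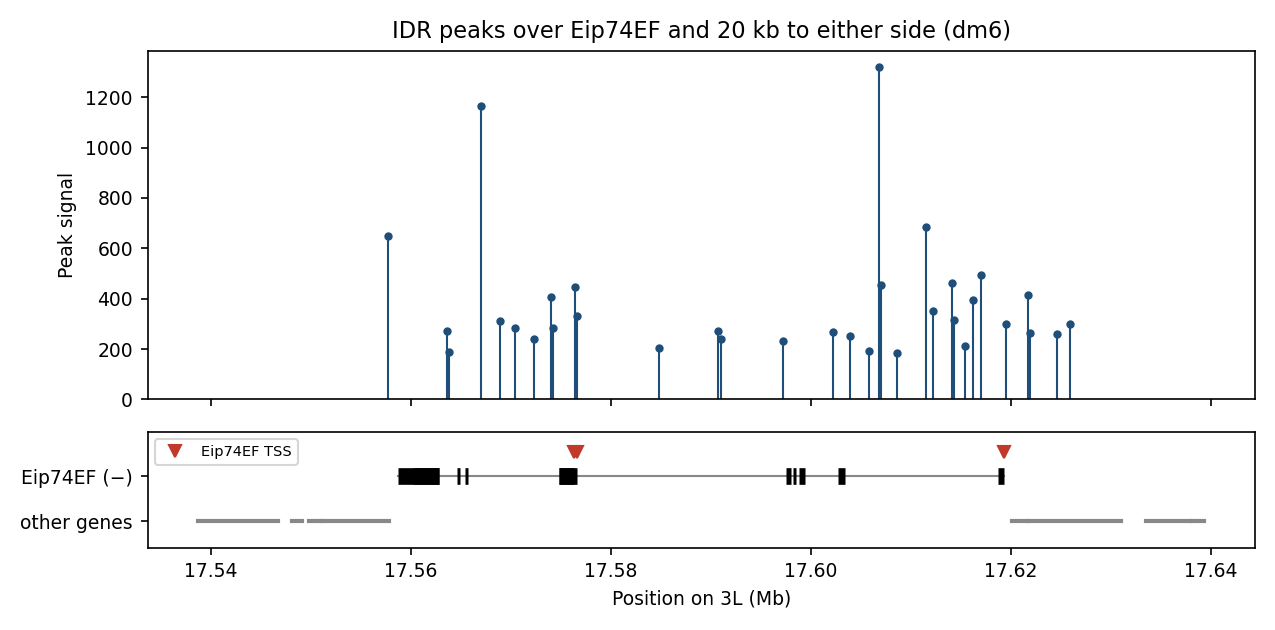
Signal of the 33 IDR peaks (y axis) over Eip74EF and 20 kb to either side against position on 3L (x axis, Mb, dm6). Below, Eip74EF exons (black boxes), its annotated TSSs (triangles) and other protein-coding genes (grey); the highest peak, with a signal of 1318, lay in an intron.

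Genes of the ecdysone response were bound widely, and mostly in introns. Of 28 listed genes, 20 (71.4%) had an IDR summit between 2 kb upstream of the gene and its end, against 45.7% in random lists matched on gene length (permutation test, two-sided, adjusted p = 0.031), and 18 (64.3%) did so among the strongest peaks of replicate 1 alone, which did not pass (permutation test, adjusted p = 0.23). With 10 kb added on either side the call was also lost (25 of 28 genes, permutation test, adjusted p = 0.054). The tagged gene Eip74EF is among the 20, and the gene body test was not rerun without it. After Eip74EF with 28 summits came the nuclear receptor genes Eip75B with 20, ftz-f1 with 15 and Hr4 with 12, the coactivator gene tai with 9 and the receptor gene Hr3 with 7. The ecdysone receptor gene EcR held 6 and chinmo, a regulator of temporal identity, held 5, among them a summit at 2L 1657311 with a signal of 1612. Hr3 had a summit at 2R 10220086 with a signal of 1310, Hr4 one at X 1947750 with 997.4, Eip75B one at 3L 17968787 with 936.3 and ftz-f1 one at 3L 18759402 with 829.6, all 4 intronic. EcR reached 499.1 and tai 441.3, both in introns. Eip78C, Hr39, vri, ImpL2 and Blimp-1 each held 3 summits, with highest signals of 592.9, 664.1, 558.3, 834.7 and 289.3. Kr-h1 and ImpE3 held 2 each (624.1 and 481.0), and br, Hr38, Hr78, Eip63F-1 and crol held 1 each (393.6, 230.1, 469.8, 247.7 and 206.8). Both ImpE3 summits, 949 and 1150 bp from its own TSS, lay within 500 bp of another gene's TSS. So did the Hr3 summit at 2R 10238230, which was 882 bp from the nearest Hr3 TSS. At promoters, 14 of the 28 (50%, 95% interval 30.6 to 69.4%) had a summit within 500 bp of a TSS, against 15.5% of other genes (Fisher's exact test, adjusted p = 0.00013 over 24 lists). These genes have many TSSs, and against random lists matched on TSS number, at 31.6%, the promoter count did not pass (permutation test, adjusted p = 0.13). It was also lost among the 2502 strongest IDR peaks, where 6 of 28 genes had a promoter summit (Fisher's exact test, adjusted p = 0.19). With all IDR peaks but without Eip74EF in the lists, 13 of 27 genes had one (48.1%, Fisher's exact test, adjusted p = 0.00043). The list of ecdysone synthesis and uptake held 1 bound promoter among 15 genes, that of the ecdysone importer gene Oatp74D (signal 287.0), and 2 among the strongest peaks of replicate 1 alone.

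Of the other lists, genes for cytosolic ribosomal proteins had the highest share of bound promoters. A summit lay within 500 bp of a TSS for 63 of 85 (74.1%, 95% interval 63.5 to 83.0%), against 15.2% of other genes (Fisher's exact test, adjusted p = 5.76e-32). Their peaks were of moderate height, the strongest being at RpS27 (3R 25247501, signal 779.0), RpL31 (2R 9587234, 687.3) and RpL30 (2L 19009238, 627.0). Mitochondrial ribosomal protein genes had 17 of 73 promoters bound (23.3%, Fisher's exact test, adjusted p = 0.20), a share that passed only against lists matched on TSS number (permutation test, adjusted p = 0.032) among the alternatives tried. Of the 13 without another gene's TSS within 1000 bp, 1 was bound (7.69%), against 11.9% of other genes. Yet the peaks at 3 genes of the full list, mRpL41 (2R 15217759, signal 2123), mRpS23 (2L 13835459, 2038) and mRpS10 (3R 15229539, 1893), were among the 30 strongest IDR peaks. Proteasome genes, with 5 of 48 (10.4%), and respiratory chain genes, with 10 of 92 (10.9%), did not differ detectably from other genes (Fisher's exact test, adjusted p = 0.57 and 0.43). Among the strongest peaks of replicate 1 alone, the respiratory chain count was 16 of 92 (17.4%), against 18.1% of other genes. The strongest promoter peaks of both lists were at Rpn9 (392.9), Rpn3 (384.9) and Rpn13 (295.0), and at Cyt-c-d (1216), ND-ASHI (628.7) and Cyt-c-p (442.9).

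Heat shock and autophagy genes also had more bound promoters than other genes. Of 11 heat shock genes, 6 were bound (54.5%, Fisher's exact test, adjusted p = 0.013), led by the small heat shock protein gene Hsp27 (3L 9383909, signal 1098), the Hsp90 gene Hsp83 (628.2) and Hsp26 (478.9). Of 20 autophagy genes, 9 were bound (45.0%, Fisher's exact test, adjusted p = 0.0084), led by Atg17 (3R 5669451, 422.5), Atg7 (367.5) and Atg2 (337.1). Neither list passed among the 2502 strongest IDR peaks (Fisher's exact test, adjusted p = 0.096 and 0.34). The autophagy list did not pass in either replicate's strongest peaks alone (Fisher's exact test, adjusted p = 0.062 in replicate 3 and 0.074 in replicate 1), nor without genes that have another gene's TSS within 1000 bp, where 1 of 5 genes was bound. The heat shock list did not pass against lists matched on TSS number (permutation test, adjusted p = 0.076) or in a 250 bp window (Fisher's exact test, adjusted p = 0.12). Of 8 genes for ETS factors, 4 were bound (50%, Fisher's exact test, adjusted p = 0.084). Of these, Eip74EF (444.8), pnt (355.7) and Ets21C (256.7) were the strongest, and aop, which encodes an ETS repressor, was the fourth. The ETS list passed in windows of 250 bp (4 of 8, Fisher's exact test, adjusted p = 0.041) and 1000 bp (5 of 8, 0.029) and without shared promoters (4 of 7, 0.025). It did not pass in the other alternatives, such as lists matched on TSS number (permutation test, adjusted p = 0.51). Nor did it pass without the tagged gene Eip74EF (3 of 7, Fisher's exact test, adjusted p = 0.22). Of 290 tRNA genes, 57 (19.7%) had a summit within 500 bp of their start, against 9.03% of all other genes (Fisher's exact test, adjusted p = 2.33e-07) and 11.7% of other genes without transposable elements (p = 0.0001). These 57 genes shared 35 summits, so neighbouring tRNA genes were not independent, and the list did not pass among the 2502 strongest peaks. The strongest were near tRNA:Tyr-GTA-1-8 (1382), tRNA:Phe-GAA-1-2 (470.4) and tRNA:Ala-TGC-2-1 (419.9).

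**Figure D5:**
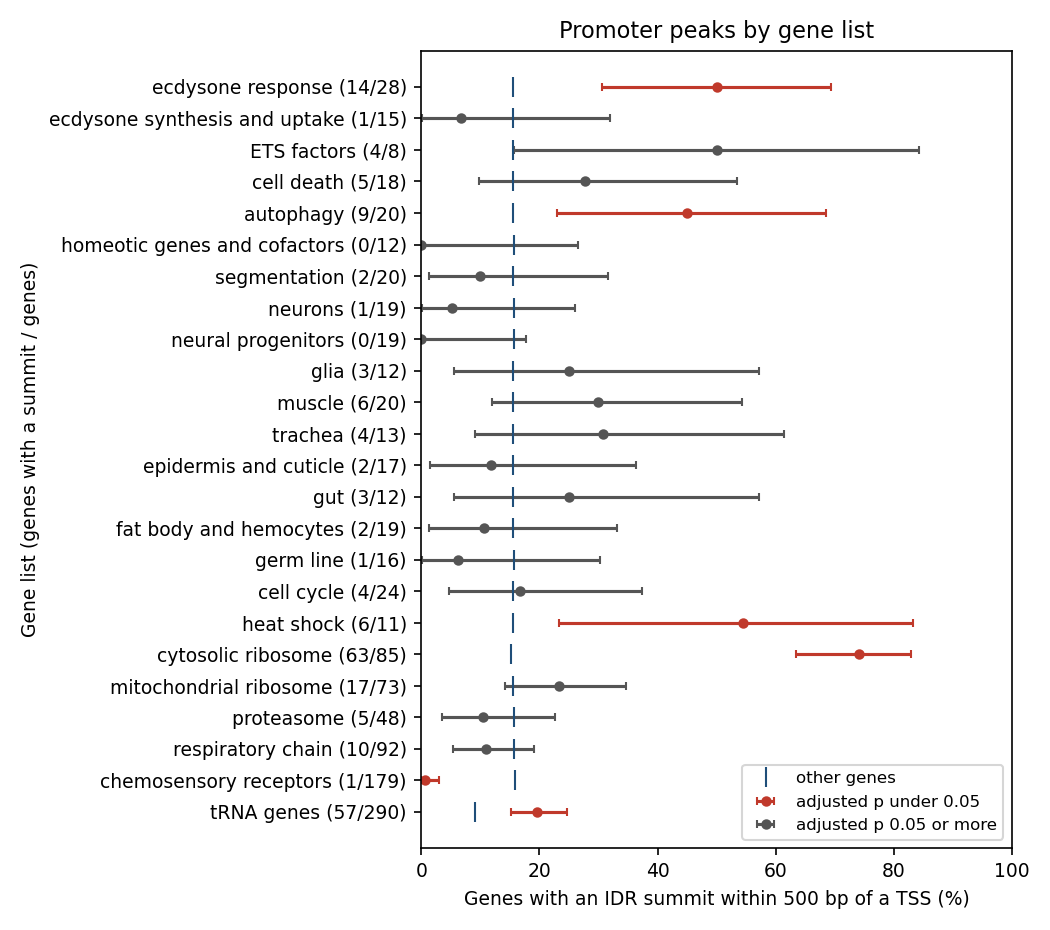
Share of genes with an IDR summit within 500 bp of a TSS (x axis, percent) for each of the 24 gene lists (y axis, with counts), as points with 95% exact binomial intervals; vertical ticks give the share in other genes. Cytosolic ribosomal protein genes lay at 74.1% and chemosensory receptor genes at 0.559%.

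Chemosensory receptor genes were nearly unbound, with 1 of 179 promoters (0.559%, 95% interval 0.0141 to 3.07%) against 15.8% of other genes (Fisher's exact test, adjusted p = 5.02e-11), that of Gr64a (signal 299.1), and 0 of 179 among the strongest peaks of replicate 3 alone. Lists of embryonic tissues and cell types did not differ detectably from other genes at promoters. Bound promoters numbered 0 of 12 homeotic genes and cofactors, which allows a share of up to 26.5% (Fisher's exact test, adjusted p = 0.43), 0 of 19 neural progenitor genes, which allows up to 17.6% (adjusted p = 0.18), and 1 of 19 neuronal genes (adjusted p = 0.55), the last being that of elav, with a signal of 1299. Against lists matched on TSS number the neuronal list passed as lower (permutation test, adjusted p = 0.045). Segmentation genes had 2 of 20 (hry, 266.7, and wg, 197.9), epidermis and cuticle 2 of 17 (knk, 393.8, and mmy, 201.1), fat body and hemocytes 2 of 19 (ush, 342.2, and Adh, 249.5) and germ line 1 of 16 (gcl, 326.5). Muscle had 6 of 20 (led by sls, 705.4, Act87E, 400.7, and Tm1, 364.0), trachea 4 of 13 (trh, 700.0, pyd, 455.7, bnl, 334.7), gut 3 of 12 (bowl, 585.5, fkh, 424.4, dve, 222.4) and glia 3 of 12 (moody, 633.4, Gli, 279.2, loco, 198.8). Cell death genes had 5 of 18 (hid, 424.3, Diap1, 288.7, drpr, 216.6) and cell cycle genes 4 of 24 (CycE, 683.4, Dp, 482.7, Cdk1, 251.4). Several of these counts moved by over 1.5 times with the strongest peaks of a single replicate, none of them past the threshold. In replicate 3 alone, glia had 5 of 12, epidermis and cuticle 4 of 17 and neurons 2 of 19. In replicate 1 alone, cell cycle had 8 of 24, epidermis and cuticle 1 of 17, segmentation 1 of 20, germ line 2 of 16 and homeotic genes 1 of 12. Among these lists in the IDR peaks the adjusted p ranged from 0.18 for neural progenitors to 1 for epidermis and cuticle. Over whole genes, with lists matched on gene length (permutation test), the calls for cytosolic ribosome (66 of 85, adjusted p = 0.0023), autophagy (13 of 20, 0.0046), heat shock (7 of 11, 0.013) and chemosensory receptors (5 of 179, lower, 0.0023) were made as well. Those for autophagy and heat shock were lost without the upstream part (permutation test, adjusted p = 0.22 and 0.39) and among the 2502 strongest IDR peaks (0.29 and 0.052), and that for heat shock also with 10 kb on either side (0.084). Mitochondrial ribosomal protein genes passed there too (22 of 73, 30.1%, against 13.5%, permutation test, adjusted p = 0.0046), though not among the strongest peaks of replicate 3 alone (21.9%, adjusted p = 0.14), among the 2502 strongest IDR peaks or without the upstream part.

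Peaks were denser in some windows than random placement gave. The densest 20 kb window, 3L 17600001 to 17620000, lay in Eip74EF and held 14 IDR peaks. The next, 2L 2160001 to 2180000, over the ETS repressor gene aop, held 13, and 3R 16220001 to 16240000, over tara, held 11, as did a window over shot. The highest count in any window of the 1000 random sets was 9 (permutation test, one-sided, p = 0.000999, the smallest possible), and 5 windows exceeded it. Summits of overlapping peaks were counted separately, while random positions were placed independently, so these counts are not numbers of separate bound regions.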

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

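The deposited pooled list holds 24996 peaks below the IDR threshold, at ranks 5005 to 30000, which the comparisons above use only for the peak density over Eip74EF, and both values given here stood out as signals in data that was otherwise left out of them. Of these peaks, 10310 (41.2%) had a summit within 100 bp in both replicate lists, against a mean of 529.2 and a maximum of 595 in 100 random placements. Reads of both replicates entered the pooled list, so part of this overlap is built in. The hexamer CGGAAG lay within 50 bp of 3.82% of the summits below the threshold and in 2.25% of their flanks, a ratio of 1.70 (exact McNemar test, p = 1.55e-24), against 7.31% and 2.31% at IDR summits. The hexamer had been picked from the scan of the IDR peaks, and this test was chosen after that result was seen.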

How the results depend on the processing

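Of the alternatives set before the data were examined, replacing the IDR peaks by the same number of top pooled peaks gave no separate values, since both sets are identical, and counting summits within 100 bp once changed nothing, since none lie that close. The latter could not test for split peaks, since 377 gaps between neighbouring IDR summits were under 500 bp. Counts of summits per gene or window may therefore include a bound region repeatedly. A single replicate list has no IDR step and its own signal scale. The k-mer alternatives, the other peak sets for clusters, the CGGAAG string, the lists without Eip74EF and the tRNA background without transposons were chosen after seeing the data. No paired analysis was possible because the samples form 1 group. The cause of the changes given here was not tested, except that a stricter threshold leaves fewer peaks by construction. The promoter share (30.9% to 51.2% over windows and peak sets), replicate overlap (53.6% to 74.8%), X to autosome ratio (0.880 to 0.964) and ETS consensus kept their direction and their side of the threshold under every alternative run, except for the consensus at promoter peaks alone (0.485%). Between 265 and 286 hexamers were higher at summits over the other peak sets; of octamers, 234 were higher and 17 lower, against 289 and 573 hexamers. With the 2502 strongest IDR peaks, the calls for introns (40.5%) and other exons (1.56%) were lost, the lists called higher fell to 1 at promoters and 2 over gene bodies, the Eip74EF locus held 19 peaks and the densest window 9. Leaving out a replicate, that is, using the other's 5004 strongest peaks, gave intron shares of 37.4% (without replicate 3, below random) and 42.9%, panel strings higher at summits of 3 and 1, and promoter signal differences of 2.86 (without replicate 3) and 10.6. Against random lists matched on TSS number, 3 lists were called higher and 2 lower, with mitochondrial ribosome (higher) and neurons (lower) newly called. Over gene bodies, 2 lists were called higher with no upstream part, and 3 higher and 2 lower with 10 kb on either side, with neural progenitors (lower) newly called. Of 52 genes named for a promoter peak, 42 had one among the 2502 strongest peaks, 51 without replicate 1 and 47 without replicate 3; of 20 ecdysone response genes with a summit, 17, 20 and 18 did. Of the further values for single strings, lists and named genes, 504 kept their side of the threshold or, for named genes, kept at least 1 summit. A named gene counted as kept even where it lost most of its summits. Of the rest, 22 were no longer past the threshold, 9 were newly past it and 21 were named genes left without a summit. The unknown depth of both libraries limits any statement on genes without a peak.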

Other observations

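Several genes outside the ecdysone response list carried as many peaks as genes on it. They were picked from a ranking made after the data had been seen. Of them, kirre is on the muscle list and aop on the list of ETS factors. Of the 13945 protein-coding genes, 26 held at least 10 IDR summits between 2 kb upstream and their end. After Eip74EF and Eip75B these were led by CG1677 (17), the overlapping pair CG46467 and Glut4EF (16 each), the cell adhesion gene kirre (16) and sbb (15). The Dpp pathway gene shn held 14, as did tara, the forkhead gene CHES-1-like held 13, and the kinase gene Raf and the Notch coactivator gene mam held 11 each. Per 10 kb, aop (5.77), CHES-1-like (4.48) and Eip74EF (4.47) stood above tara (3.82) and Eip75B (1.73). Several of these genes are long, and the counts were not tested.

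Along the pooled list, ranked by signal, the share of promoter summits fell from 49.8% in the first 500 peaks to 39.3% just above the IDR threshold and 15.8% in the last 10000, while coding exons never held more than 1.96%. CGGAAG was at 6.2% of the first 500 summits, 10.8% of the next 500 and 3.56% of the last 10000. GC content was lowest, at 30.8%, in the first 500. The shares of CGGAAG were 6.83% at promoter, 7.37% at intron and 7.56% at intergenic IDR summits, each not detectably different from all other IDR summits (Fisher's exact test, p = 0.29, 0.91 and 0.75).

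For the 3 patterns weighed below, the tests of housekeeping promoters, of shared promoters and of GC content beyond 100 bases from summits were chosen only after the result was seen. The design holds 1 group, so no biological explanation was tested by comparing groups, and the sequence tests stand in as hypotheses.

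The first pattern was the density of peaks over Eip74EF. Extra copies in the tagged line may add to it: with the locus signal divided by 2, 11 peaks would pass the threshold and the density would stay above 95.5% of long genes, and a divisor of 2.2 was the smallest to bring it below the 95th percentile. Whether the line holds a further copy of the locus is not given in the sources used here and both samples are of that line, so this cannot be told apart from binding. The signal is relative to a control library, so dividing it stands for extra copies only where that library lacks them. The control library was not examined here. A richness in the hexamer CGGAAG is argued against, since it occurred 0.288 times per kb over the locus, above 49.6% of long genes (median 0.289). The hexamer lay at 1 of the 33 summits there (3.03%, against 7.34% at other IDR summits, Fisher's exact test, p = 0.51). Other ETS-type strings were not counted over the locus.

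The second pattern was the binding of cytosolic ribosomal protein promoters. Respiratory chain and proteasome genes had such peaks less often: 15 of 140 (10.7%, 95% interval 6.12 to 17.1%) had a promoter peak (16 of 92 respiratory chain and 6 of 48 proteasome genes in replicate 1 alone). Both lists were drawn by symbol pattern and expression was not measured here, so genes with little expression in embryos may be among them. A signal at all abundantly expressed housekeeping promoters alike is therefore left undecided, as is a signal that grows with expression. Promoters shared with a neighbour do not account for the binding at ribosomal protein genes, since 20 of the 31 of these genes without one (64.5%, adjusted p = 1.59e-10, Fisher's exact test) were bound. A candidate explanation is direct binding through ETS cores, since 12 of 74 summits there held CGGAAG (16.2%, 95% interval 8.67 to 26.6%), against 6.49% of the other promoter summits (Fisher's exact test, two-sided, p = 0.0036). Most of these summits held no CGGAAG, so through that hexamer the hypothesis covers a minority of them. Other ETS-type strings were not sought at these summits. CGGAAG had been picked from the scan of the IDR peaks, which include these summits. It was not set against their own flanks or against hexamers of its base composition there, so a difference in composition of these promoters is not excluded.

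The third pattern was the AT-rich sequence at summits. The choice of location classes is argued against, since GC within 50 bases of summits was 35.9%, below the lowest (40.9%) of 1000 sets of random positions matched on arm and class. A bias reaching beyond 100 bases is left undecided. Between 100 and 200 bases from summits GC was 42.2%, above the highest (42.05%) of the matched sets. Yet GC still rose with distance there, from 41.6% and 41.8% at 120 bases on the left and right to 42.7% on both sides at 200 bases. The sets were not matched on the GC of the wider surroundings, so they could hide a shortfall. A bias on the mean GC of fragments of about 400 bases, to which the centre alone contributes, is left undecided: within 200 bases of summits GC was 39.8%, but the AT-rich centre alone would bring it to 40.2%, already below the lowest matched set (41.2%), so that test could not have come out otherwise. GC and signal had a Spearman correlation of -0.18 across the 5004 regions, which are not independent replicates.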
